A study of Mus musculus with 18 samples.

How the data were processed

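The samples were 9 total RNA and 9 small RNA libraries of CD4+ T cells from 3 groups of 3, naive, Hopx-low and Hopx-high, as the sample titles give them. Per the labels' protocols, RNA was purified with Trizol and a mirVana kit, ribosomal RNA was depleted, and barcoded Ion Torrent libraries were made for total and small RNA. The submitters' processing notes name the mm10 build and bedtools. The aligner, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies cannot be told apart.

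The authors deposited 1 table per assay with a signal value per feature and library, and no column was without a sample. From the values, each deposited signal equals the aligned bases over a feature plus 1, times the mean library total divided by that library's total: after division by the smallest value in its column, 100% of values came out whole within a tolerance of 1e-06. The low values sat near single read lengths (medians of 118 to 128 bases in total RNA and 21 to 22 in small RNA), so the whole numbers are covered bases and not reads, and no test for counts was used. The deposited floor for a feature without coverage therefore depends on a library's depth. For this reason each value was turned back into bases and expressed as bases per megabase covered in its library. This step was chosen after the values were seen, departs from the planned log2 of the deposited value plus 1, and the planned scale is given among the alternatives.

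A pseudocount of 1 was added, values were taken to log2, and features with a level of at least 1 in at least 3 libraries were tested with limma (lmFit and eBayes with trend and robust settings; limma 3.58.1, R 4.3.3), with all 9 libraries of an assay sharing an estimate of the spread and adjusted p below 0.05 by the Benjamini-Hochberg method. This left 11320 of 23219 features in total RNA and 510 of 2220 in small RNA, of which 8904 and 1397 were at 0 in every library. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9. Feature names were matched to a RefSeq gene table of GRCm38.p6, which is the mm10 build (23075 and 1206 names matched), and positions come from it. Depth ranged from 105 to 329 megabases per total RNA library and from 11.6 to 36.2 megabases per small RNA library. Correlations of log2 levels within a group were 0.938 to 0.964 in total RNA and 0.963 to 0.982 in small RNA. Between groups they were 0.842 to 0.942 and 0.910 to 0.975, so the ranges overlapped. At most 0.0740% and 3.78% of features had equal base coverage in libraries of a group, so no library was treated as deposited more than once.

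Gene lists, cell type marker lists and microRNA families were fixed before the data were examined. The 35 lists covered T-cell states and processes and markers of B cell, plasma cell, CD8, NK and innate lymphoid, dendritic, monocyte and macrophage, neutrophil, erythroid, platelet, stromal, gamma-delta and NKT and CD4 T cells. They were tested with camera at a preset correlation of 0.01 where at least 5 members were measured (29 lists), adjusted over lists within a comparison, and again with an estimated correlation and with fry. Named genes were chosen by a rule fixed beforehand: Hopx; the 10 largest rises and falls among called features whose libraries did not overlap and whose mean was at or above the median; up to 4 members of each list with the smallest adjusted p; and a fixed set of T-cell genes. For microRNAs the rule took the 8 largest rises and falls among called ones with a mean at or above the median, whether or not libraries overlapped. It also took up to 2 members per family. Values of some genes that the rule named are not reported here. By chance 10% of features would have groups of 3 that do not overlap; 29.2%, 39.1% and 16.7% did in total RNA for Hopx-low against naive, Hopx-high against naive and Hopx-high against Hopx-low, and 161, 209 and 170 of 510 in small RNA.

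The alternatives planned were upper-quartile scaling, quantile normalization, limma without trend or robust settings, a test against a fold of 1.2, no filter, a filter of 5, pseudocounts of 0.1 and 5, the replicate number as a block, only the 6 libraries compared, each library left out in turn and other thresholds. Added after the data were seen were the deposited scale, totals without Lars2 or without Lars2 and histones, leaving out both libraries richest in Lars2, only replicates 1 and 2, annotated microRNAs alone, upper-quartile scaling and quantile normalization of the list and family results, lists without Lars2 in the totals, and each library left out in turn for families. The tests were first run on simulated coverage with known changes. For Hopx-low against naive over 11197 simulated total RNA features, 60.6% of features changed 4-fold, 14.9% of those changed 2-fold and 1.49% of those changed 1.5-fold were recovered, with 1 false call among 52; false calls were 3 among 49 for Hopx-high against naive and 4 among 44 for Hopx-high against Hopx-low, 6.12% and 9.09% against a threshold of 5%. For the same comparison over 493 small RNA features the shares were 40.0%, 15.0% and 0%, with 0 false calls among 11; there were 2 among 20 and 0 among 14 for the other comparisons.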

Results

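The series measured RNA in CD4+ T cells taken from the lymph nodes and spleen of C57BL6 mice. Chimeric antibodies that carry an antigen to dendritic cells, the cells that present antigen to T cells, had been injected into the peritoneum 5 days before collection. The T cells fell into 3 groups of 3 libraries each: naive cells, activated cells with a low level of Hopx, and activated cells with a high level of Hopx. Hopx is a homeodomain protein that does not itself bind DNA. Each group was measured by total RNA sequencing after ribosomal RNA depletion and by small RNA sequencing, which gave 18 libraries in all. The comparisons ask how activated T cells of each Hopx level differed from naive cells and from each other. The labels do not say whether libraries came from separate animals, so the p-values measure only the spread between these libraries.

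Levels are given as bases per megabase covered in a library, as mean ± SD over 3 libraries of a group unless stated otherwise. Total RNA libraries held 105 to 329 megabases of coverage over 23219 features, and small RNA libraries held 11.6 to 36.2 megabases over 2220 features. A level of 1 corresponded to roughly 0.832 to 2.61 reads in total RNA and 0.552 to 1.65 reads in small RNA, so levels of a few units rest on few reads. Fold changes are on the scale log2(level + 1), which understates the change of low genes, and are followed by their standard error. The largest rises and falls are ranked only among called features that averaged at or above the median, here termed ranked features. In total RNA their libraries also did not overlap between the groups, which the rule for microRNAs did not require. Less abundant features changed more in several cases. Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 17.98% of the bases in Hopx-low replicate 1 and 18.9% in Hopx-high replicate 3, against 0.525% to 6.55% in the other total RNA libraries. Those libraries were also the shallowest in total RNA, at 105 and 110 megabases, against 206 to 329 in the others. What these Lars2 bases came from was not tested, so they need not reflect expression of the gene. Replicate 3 of each group carried Xist coverage and none of the Y-linked Ddx3y, whereas replicates 1 and 2 of each group showed the reverse, so each group held libraries from cells of different sex, balanced across groups. Small RNA naive replicate 2, the shallowest at 11.6 megabases, held 87.4% of its bases in annotated microRNAs, against 94.4% to 98.99% in the others. Mir5121 took 9.12% of its bases, against 0.733% to 2.72%. Without this library limma called 62 small RNA features in Hopx-low and 160 in Hopx-high against naive cells, compared with 70 and 158. Lars2, Xist, Ddx3y and Mir5121 were picked after their values were seen.

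Hopx itself followed the group labels. Its level was 0.971 ± 0.894 in naive, 6.995 ± 0.948 in Hopx-low and 27.8 ± 5.77 in Hopx-high cells. The log2 fold change was 2.14 ± 0.44 for Hopx-low against naive (adjusted p = 0.0025) and 3.97 ± 0.44 for Hopx-high against naive (adjusted p = 4.2e-07). Hopx-high exceeded Hopx-low by 1.84 ± 0.44 (adjusted p = 0.025). The gene lies on chromosome 5, 77086986 to 77115123, in the GRCm38.p6 assembly, from which all positions here are taken. The labels name the groups by their level of Hopx and do not say how the cells were told apart, so this difference checks the labels and is not a separate finding.

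**Figure D1:**
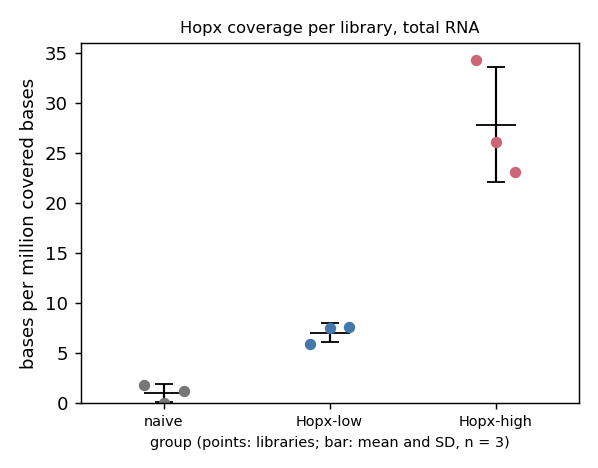
Hopx coverage in each total RNA library (y axis, bases per megabase covered) by group (x axis), with points for libraries and bars for the mean and SD of 3. The 3 Hopx-high libraries lie between 23.1 and 34.2, above the Hopx-low libraries at 5.90 to 7.59 and the naive libraries at 0 to 1.76.

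In Hopx-low against naive cells, the largest rises were in Lad1, which encodes a filament-anchoring protein (log2 fold change 7.13), and the Wnt ligand gene Wnt10a (6.45). Il2rb, a subunit of the interleukin 2 and 15 receptors, stood at 11.5 ± 4.70 in naive and 654 ± 14.96 in Hopx-low cells (log2 fold change 5.80 ± 0.23, adjusted p = 1.2e-13). Tnfrsf9, the costimulatory receptor 4-1BB, stood at 2.57 and 218 ± 40.9. Eomes, a T-box transcription factor of effector cells, stood at 0.117 and 59.2 ± 16.4, and Ikzf2, which encodes Helios, at 0.588 and 70.8 ± 11.6. These were among the 10 largest rises of ranked features, with Fibcd1 (5.99), the inhibitory receptor gene Lag3 (5.35), the follicle-homing receptor gene Cxcr5 (5.23) and Adamtsl2 (5.05). Ly6c1, a surface antigen of T cells, fell from 300.0 ± 45.5 to 43.2 ± 8.83 (log2 fold change -2.78 ± 0.24, adjusted p = 2.5e-08). The other largest falls of ranked features were in Adamts14 (-2.73), the interleukin 7 receptor gene Il7r (-2.56), Myo6 (-2.48), Pdlim4 (-2.36), the interferon-inducible GTPase gene Tgtp1 (-2.28), the perforin gene Prf1 (-2.13), the cytokine signalling suppressor gene Socs3 (-2.00), Sgk1 (-1.92) and Oas2 (-1.87). Limma called 950 of 11320 features, 538 higher and 412 lower at an adjusted p below 0.05. The commoner direction turned with only the 6 libraries compared, 537 higher and 578 lower, and the split was 573 and 180 without Hopx-low replicate 1. Without naive replicate 1 the count was 576, and with only replicates 1 and 2 it was, to 2 digits, 5.0e+02, an alternative chosen after the data were seen.

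Lists of regulatory, inhibitory receptor and anergy genes were called higher. They share members, such as Ctla4 (regulatory and inhibitory) and Lag3, Nr4a1 and Cd5 (inhibitory and anergy), so their calls are not separate results. Of 15 measured genes of the regulatory T cell list, 12 rose and 0 fell (14 rose adjusted over the list alone), and the list was called higher (camera, adjusted p = 4.6e-24; adjusted p = 0.0075 with an estimated correlation). Ctla4, which encodes an inhibitory receptor, stood at 0.602 in naive and 36.7 ± 4.27 in Hopx-low cells, and Foxp3, the defining factor of regulatory T cells, at 1.42 and 9.82 ± 6.05 (adjusted p = 0.0078). In the list of inhibitory receptors and exhaustion 9 of 16 genes rose (9 adjusted over the list alone; camera, adjusted p = 1.9e-14; adjusted p = 0.030 with an estimated correlation), among them Pdcd1, which encodes PD-1 (log2 fold change 2.54 ± 0.26). The anergy list had 11 of 20 genes higher and 2 lower (11 and 3 adjusted over the list alone; camera, adjusted p = 7.9e-11). That call was lost at adjusted p = 0.11 with an estimated correlation. Its risen members included Egr2 (3.00), Egr3 (3.00) and Nr4a1 (3.61), transcription factors induced by T-cell receptor signals, and Cd5 (1.36), a receptor that dampens those signals.

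Follicular helper genes rose in 9 of 16 cases and fell in 0 (11 rose adjusted over the list alone; camera, adjusted p = 1.4e-15; adjusted p = 0.039 with an estimated correlation). Bcl6, the factor that directs this fate, stood at 17.8 ± 1.21 in naive and 75.02 ± 25.7 in Hopx-low cells. In the T helper 1 and effector list 8 of 19 genes rose and 2 fell, with the same counts adjusted over the list alone (camera, adjusted p = 2.8e-07; adjusted p = 0.11 with an estimated correlation). Its members included Irf8 (3.16), Bhlhe40 (3.95), Cxcr3 (3.71) and Tbx21, which encodes T-bet (1.98, adjusted p = 0.034), whereas Prdm1, which encodes Blimp-1, fell (-1.51). Of the T helper 2 list, 3 of 9 genes rose and 0 fell, and of the T helper 17 list 2 of 8, each with the same counts adjusted over the list alone. Both lists were called higher (camera, adjusted p = 0.0092 and 0.0080) and neither with an estimated correlation (adjusted p = 0.24 for both). Gata3, the defining factor of T helper 2 cells, stood at 99.3 ± 6.57 and 89.6 ± 21.03 and did not pass the test. Ifng, the main T helper 1 cytokine, was listed at 0 in the naive and Hopx-low libraries, and Il2 was below the level needed for testing. In the activation and memory list 10 of 28 genes rose and 5 fell (11 and 6 adjusted over the list alone; camera, adjusted p = 0.00027; adjusted p = 0.23 with an estimated correlation), with Hopx itself among the members that rose and Cd44, an adhesion receptor of antigen-experienced cells, at 37.4 ± 14.9 and 108 ± 30.3.

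The lists of cell division genes were called higher. Of 49 proliferation genes 30 rose and 0 fell (33 rose adjusted over the list alone; camera, adjusted p = 9.5e-27; adjusted p = 0.039 with an estimated correlation). Of 61 replication-dependent histone genes 55 rose (58 adjusted over the list alone; camera, adjusted p = 9.6e-88; adjusted p = 0.030 with an estimated correlation). Mki67, which encodes the Ki-67 antigen of cycling cells, stood at 0.808 in naive and 16.9 ± 7.07 in Hopx-low cells. Histone genes resemble one another in sequence, so values of single members are uncertain. Their summed share of bases does not depend on how reads were divided between them if each read was counted once, which is not known. The summed share was 1.05% ± 0.226 in naive and 2.34% ± 0.269 in Hopx-low cells. Of 25 immediate early and stress genes 7 rose (9 adjusted over the list alone; camera, adjusted p = 2.1e-08; adjusted p = 0.19 with an estimated correlation), among them Egr1 (1.70) and Myc, a growth-promoting transcription factor (1.17). Of 23 glycolysis genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera, adjusted p = 0.00027; adjusted p = 0.23 with an estimated correlation), with Hk2, a hexokinase, higher (2.36 ± 0.42) and the pyruvate dehydrogenase kinase gene Pdk1 lower (-1.35 ± 0.22). In oxidative phosphorylation 1 of 55 genes rose, also adjusted over the list alone, but 6 with upper-quartile scaling (Atp5g3; camera, adjusted p = 0.0011; adjusted p = 0.41 with an estimated correlation). Of 26 apoptosis regulators 6 rose (7 adjusted over the list alone; camera, adjusted p = 0.0050; adjusted p = 0.42 with an estimated correlation), among them Bcl2l1, which encodes the survival factor Bcl-xL (1.94).

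The lists of resting T cells and of the interferon response were called lower. In the naive and quiescence list 11 of 28 genes fell and 2 rose (14 and 2 adjusted over the list alone; camera, adjusted p = 0.00045; adjusted p = 0.41 with an estimated correlation). Klf2, which maintains quiescence, fell from 702 ± 123 to 311 ± 66.7, and S1pr1, a receptor for exit from lymphoid tissue, from 1015 ± 243 to 450.5 ± 107. Of 46 interferon-stimulated genes 18 fell and 0 rose (32 fell adjusted over the list alone; camera, adjusted p = 4.3e-11; adjusted p = 0.23 with an estimated correlation), among them Irf7 (-1.13), Gbp7 (-1.87) and Ly6a (-1.42). Homing and adhesion receptors went both ways, with 6 of 22 higher and 8 lower (7 and 8 adjusted over the list alone), and so did T-cell receptor signalling, with 5 of 33 higher and 5 lower (5 and 6 adjusted over the list alone). Neither list was called by camera (adjusted p = 0.073 and 0.99, against 0.024 and 0.77 by fry).

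Of the lists that follow, camera called only the plasma cell list in this comparison. The cytotoxic granule and NK receptor list had 0 of 11 genes higher and 1 lower, Prf1. Cytosolic ribosomal proteins had 0 of 75 higher and 2 lower, Rps24 and Rps4x, and 0 adjusted over the list alone. Cholesterol synthesis had 0 of 22 in either direction. Histone deacetylases and chromatin silencing had 2 of 35 higher, Dnmt3a and Uhrf1, and 1 lower, Sirt1. The noncoding RNA list had 2 of 20 lower, Malat1 and Neat1 (3 adjusted over the list alone). Among markers of other cell types, B cell and monocyte and macrophage markers had 0 of 15 changed each, erythroid markers 0 of 6, and dendritic cell markers 1 of 7, the interferon-induced Bst2, lower. Plasma cell markers had 1 of 6 higher, Irf4, and 1 lower, Prdm1, both of which T cells also use (camera, adjusted p = 0.012; adjusted p = 0.24 with an estimated correlation). Of the lists with fewer than 5 measured genes, CD8 markers had 1 of 2 lower, Cd8b1 (-0.98), and NK and innate lymphoid markers 1 of 4 higher, Eomes. Neutrophil markers had 0 of 2 changed, and the single measured platelet, stromal and gamma-delta genes did not pass. Of 5 CD4 T cell identity genes, Cd3g fell (-0.88 ± 0.26), while Cd4 stood at 1033 ± 76.6 and 858 ± 207.

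**Figure D2:**
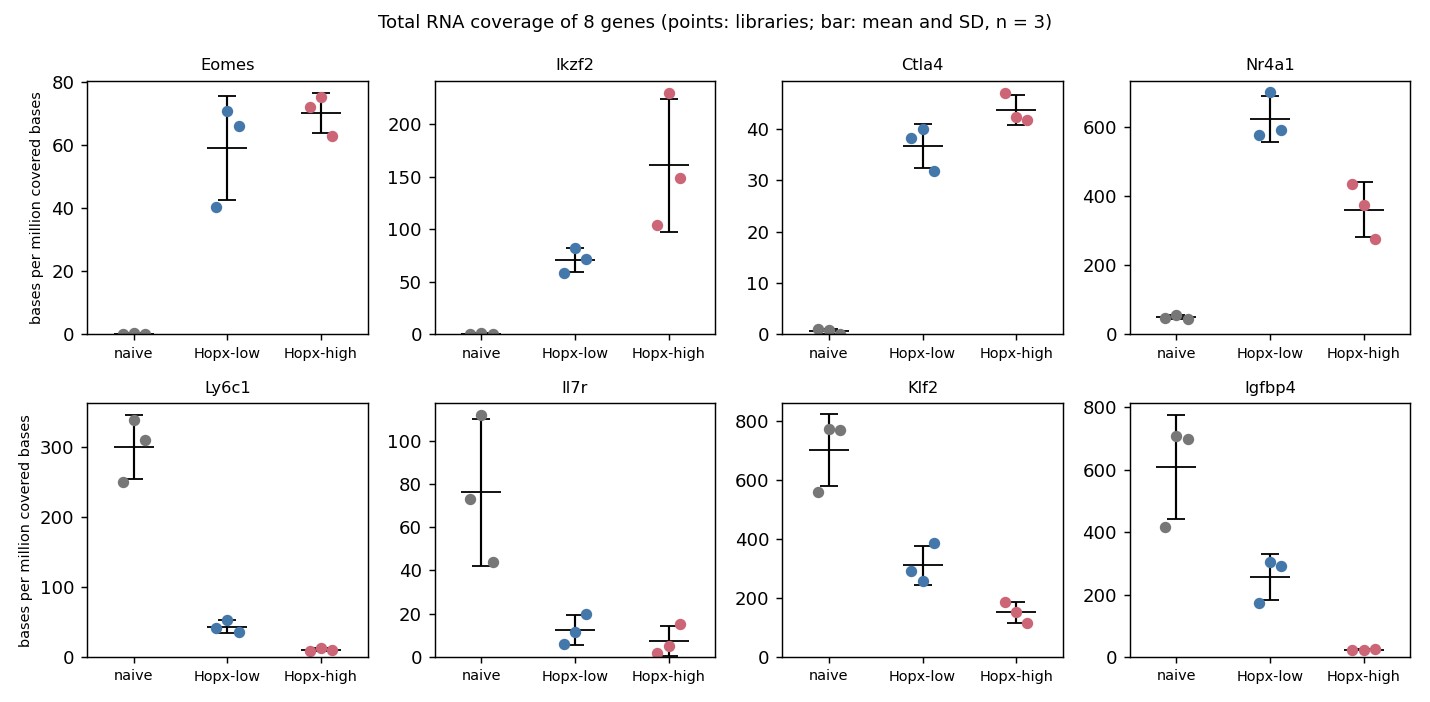
Coverage of 8 genes in each total RNA library (y axes, bases per megabase covered, each from 0) by group (x axis), with points for libraries and bars for the mean and SD of 3. Eomes, Ikzf2, Ctla4 and Nr4a1 were higher in both activated groups than in naive cells, and Ly6c1, Il7r, Klf2 and Igfbp4 were lower; Igfbp4 averaged 609, 256 and 23.5.

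In Hopx-high against naive cells, most of the leading genes were those named above. Wnt10a, which encodes a secreted Wnt ligand, stood at 0.546 in naive and 304 ± 42.6 in Hopx-high cells (log2 fold change 7.68 ± 0.28, adjusted p = 4.2e-15), and Cxcr5 at 5.08 ± 1.42 and 476 ± 82.6 (6.30 ± 0.23). The 10 largest rises of ranked features also held Lad1 (7.23), Fibcd1 (6.88), Ikzf2 (6.68), Il2rb (6.09), Endod1 (6.03), Eomes (from 0.117 to 70.2) and the histone genes Hist1h3c (6.76) and Hist1h1b (6.64). Pdlim4, a cytoskeletal adaptor, fell from 143.8 ± 19.1 to 2.97 ± 2.23 (log2 fold change -5.36 ± 0.37, adjusted p = 2.2e-10) and Igfbp4, an insulin-like growth factor binding protein, from 609 ± 167 to 23.5 ± 1.93 (-4.60 ± 0.23). The other largest falls of ranked features were in Adamts14 (-5.09), Ly6c1 (-4.72), Myo6 (-4.17), Socs3 (-3.81), Sorcs2 (-3.58), Il7r (-3.49), Ggt5 (-3.48) and Sgk1 (-3.32). Limma called 2666 of 11320 features, 952 higher and 1714 lower. With libraries scaled to equal upper quartiles the split was 1418 higher and 1134 lower, with quantile normalization 1337 of 2643 were higher, and the median of all tested features moved from -0.29 to -0.08, so which direction was commoner depended on the scaling. The count was 1754 without naive replicate 1, 1710 without Hopx-high replicate 3 and 1126, 617 higher and 509 lower, with only replicates 1 and 2.

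Regulatory T cell, inhibitory receptor and follicular helper lists were called higher here too. The inhibitory receptor list shares Ctla4, Tigit and Entpd1 with the first and Pdcd1, Tox, Tox2 and Cd200 with the last. The genes that rose were 12 of 15 regulatory T cell genes (12 adjusted over the list alone), 9 of 16 inhibitory receptor genes (9 adjusted over the list alone) and 12 of 16 follicular helper genes (12 adjusted over the list alone), with 0 lower in each. All 3 lists were called (camera, adjusted p = 3.0e-18, 8.7e-13 and 4.9e-16) and also with an estimated correlation (adjusted p = 0.016, 0.031 and 0.037). Foxp3 stood at 12.2 ± 5.73 (log2 fold change 2.40 ± 0.48), Pdcd1 at 101.1 ± 9.42 (3.37 ± 0.26), Bcl6 at 102 ± 20.9 (2.43 ± 0.27) and Tox2, a regulator of follicular helper cells, at 23.5 ± 0.958 (4.50 ± 0.40). In the T helper 1 and effector list 10 of 19 genes rose and 4 fell (10 and 5 adjusted over the list alone; camera, adjusted p = 2.6e-06; adjusted p = 0.14 with an estimated correlation), with Tbx21 at 6.80 ± 5.55 (2.08 ± 0.57) and Ccl5, a chemokine of effector cells, at 5.81 ± 2.45 (2.51 ± 0.50). The anergy list had 11 of 20 higher and 2 lower (11 and 3 adjusted over the list alone; camera, adjusted p = 1.2e-07; adjusted p = 0.19 with an estimated correlation), with Egr2 higher (2.38 ± 0.22) and Ndrg1, a stress-responsive gene, lower (-1.77 ± 0.39). Of 28 activation and memory genes 15 rose and 5 fell, with the same counts adjusted over the list alone (camera, adjusted p = 3.4e-07; adjusted p = 0.14 with an estimated correlation).

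Cell division genes rose in most cases. Of 49 proliferation genes 42 rose (46 adjusted over the list alone; camera, adjusted p = 1.2e-42; adjusted p = 0.016 with an estimated correlation) and of 61 histone genes 60 rose, also adjusted over the list alone (camera, adjusted p = 9.5e-108; adjusted p = 0.016 with an estimated correlation). Aurkb, a mitotic kinase, stood at 0.146 in naive and 38.2 ± 6.78 in Hopx-high cells, and Mki67 at 0.808 and 82.9 ± 45.3. Resting-cell genes fell in 15 of 28 cases and rose in 2 (19 and 2 adjusted over the list alone; camera, adjusted p = 2.5e-06; adjusted p = 0.29 with an estimated correlation); Satb1, a chromatin organizer, fell from 811 ± 43.97 to 299 ± 55.7. Interferon-stimulated genes fell in 29 of 46 cases and rose in 0 (34 fell and 1 rose adjusted over the list alone; camera, adjusted p = 1.4e-09; adjusted p = 0.29 with an estimated correlation). Ribosomal protein genes fell in 23 of 75 cases (25 adjusted over the list alone; camera, adjusted p = 0.012; adjusted p = 0.58 with an estimated correlation), but with upper-quartile scaling 6 fell and 2 rose, and the list was not called (camera, adjusted p = 0.12). Of 15 B cell markers 4 were higher, also adjusted over the list alone (camera, adjusted p = 8.0e-06, and 0.29 with an estimated correlation). Their mean log2 level was 3.29 in naive replicate 2, against 1.75 and 2.14 in the other naive libraries and 3.15 in Hopx-high replicate 1. Of 15 monocyte and macrophage markers 2 were higher (4 adjusted over the list alone; 5 with upper-quartile scaling; camera, adjusted p = 0.0021; adjusted p = 0.29 with an estimated correlation). Cd8b1, a marker of CD8 T cells, fell (-1.69 ± 0.23).

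Of 23 glycolysis genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera, adjusted p = 0.0041; adjusted p = 0.29 with an estimated correlation). Of 26 apoptosis regulators 7 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.0041; adjusted p = 0.39 with an estimated correlation). Oxidative phosphorylation was called with Atp5g3 alone of 55 genes higher, also adjusted over the list alone, but 10 with upper-quartile scaling and 7 with quantile normalization (camera, adjusted p = 0.011; adjusted p = 0.47 with an estimated correlation). The T helper 17 list was called with Irf4 and Batf, factors also used by other activated T cells, higher among 8, also adjusted over the list alone (camera, adjusted p = 0.015; adjusted p = 0.29 with an estimated correlation). The plasma cell list was called with Irf4 and Derl3 higher and Prdm1 lower of 6 (3 and 1 adjusted over the list alone; camera, adjusted p = 0.026, but 0.11 with upper-quartile scaling; adjusted p = 0.29 with an estimated correlation). The lists of T helper 2, immediate early and stress, homing, T-cell receptor signalling, chromatin silencing, noncoding RNA, cytotoxic granule, cholesterol synthesis, dendritic cell, erythroid and CD4 identity genes were not called by camera. Fry called T helper 2 (adjusted p = 0.039) and homing and adhesion (adjusted p = 0.020). Of 22 homing and adhesion genes 9 rose and 9 fell, also adjusted over the list alone. Ifng was above 0 in a single Hopx-high library.

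In Hopx-high against Hopx-low cells, the histone and proliferation lists were called higher. Of 61 histone genes 58 rose (60 adjusted over the list alone) and their summed share of bases was 6.42% ± 0.730 in Hopx-high against 2.34% ± 0.269 in Hopx-low cells. Of 49 proliferation genes 17 rose (36 adjusted over the list alone; 27 with upper-quartile scaling and 24 with quantile normalization), with Mki67 at 16.9 ± 7.07 in Hopx-low and 82.9 ± 45.3 in Hopx-high cells (log2 fold change 2.16 ± 0.46, adjusted p = 0.011). Both lists were called (camera, adjusted p = 3.8e-143 and 2.2e-38) and also with an estimated correlation (adjusted p = 0.019 and 0.032). Among ranked features the 10 largest rises were Mki67 and 9 histone genes, from Hist1h3b (2.49) and Hist1h3c (2.29) to Hist1h3h (2.06). The less abundant Nkg7 and S100a4 rose more (3.08 and 2.78). The largest falls of ranked features were in Igfbp4 (-3.35 ± 0.23, adjusted p = 1.6e-08), Pdlim4 (-3.00), Adamts14 (-2.36), Sorcs2 (-2.24), Cyp2s1 (-2.01), Ly6c1 (-1.95), Socs3 (-1.81), Ggt5 (-1.76), Padi2 (-1.70) and Myo6 (-1.70). Limma called 242 of 11320 features, 138 higher and 104 lower, but 176 of 298 lower on the deposited scale and 76 higher and 100 lower without both libraries richest in Lars2. With only replicates 1 and 2 it called 71. The count was, to 2 digits, 1.5e+02 without Hopx-low replicate 2, 133 without Hopx-low replicate 3 and 127 without Hopx-high replicate 3, and most calls were lower without Hopx-low replicate 1, 177 of 278, or without Hopx-high replicate 2, 135 of 229.

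**Figure D3:**
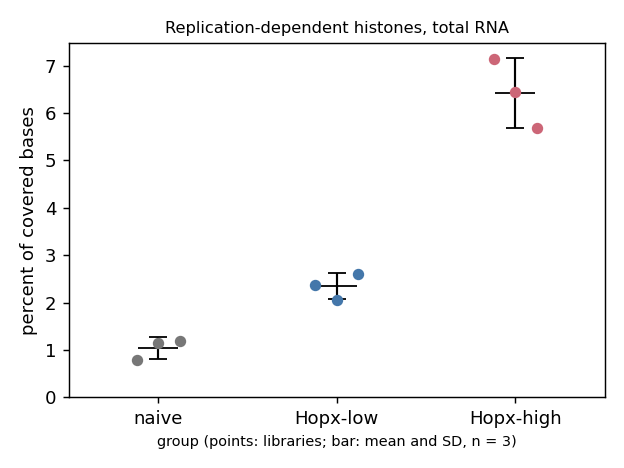
Summed share of covered bases in replication-dependent histone genes (y axis, percent) in each total RNA library by group (x axis), with points for libraries and bars for the mean and SD of 3. The Hopx-high libraries lie at 5.68% to 7.14%, the Hopx-low libraries at 2.06% to 2.60% and the naive libraries at 0.786% to 1.19%.

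Nr4a1 and Myc, transcription factor genes, were lower in Hopx-high than in Hopx-low cells. Nr4a1 stood at 624 ± 67.4 in Hopx-low and 362 ± 80.5 in Hopx-high cells (-0.80 ± 0.19, adjusted p = 0.025) and Myc at 376 ± 42.4 and 192 ± 48.8 (-0.99 ± 0.20, adjusted p = 0.0087). Of 25 immediate early and stress genes, Myc alone passed (7 fell adjusted over the list alone), and the list was called lower (camera, adjusted p = 2.1e-07; adjusted p = 0.30 with an estimated correlation). Of 28 resting-cell genes 6 fell (8 adjusted over the list alone; camera, adjusted p = 4.2e-07; adjusted p = 0.33 with an estimated correlation), among them Klf2 (-1.04) and the gut-homing receptor gene Ccr9 (-1.81). Of 28 activation and memory genes 4 rose (6 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.00028; adjusted p = 0.30 with an estimated correlation), S100a4 (2.78), Anxa2 (1.57), Lgals1 (0.97) and Hopx itself. Of 16 follicular helper genes 2 rose, Cxcr5 (1.07) and Slamf6 (1.03) (3 adjusted over the list alone; camera, adjusted p = 9.5e-07; adjusted p = 0.26 with an estimated correlation). Of 19 T helper 1 and effector genes 2 rose, also adjusted over the list alone: Cxcr3, a receptor of effector T cells, from 22.4 ± 2.996 to 77.8 ± 22.995, and Ccl5 from 0.399 ± 0.472 to 5.81 ± 2.45, while the list was not called (camera, adjusted p = 0.078). Nkg7, a cytotoxic granule gene, was listed at 0 in the naive libraries and stood at 0.637 ± 0.562 and 12.3 ± 1.94 (3.08 ± 0.47). Of the regulatory T cell list 0 of 15 passed (1 rose and 1 fell adjusted over the list alone; camera, adjusted p = 0.063), and Foxp3, Bcl6, Tbx21, Pdcd1 and Egr2 did not differ past the threshold.

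The lists of B cell markers and of monocyte and macrophage markers were called higher in Hopx-high than in Hopx-low cells, though neither with an estimated correlation. Of 15 B cell markers 3 passed (10 adjusted over the list alone; 5 with upper-quartile scaling), among them the B-cell receptor component Cd79b at 4.16 ± 0.829 and 20.6 ± 5.03 and Cd22 at 4.14 ± 3.24 and 20.8 ± 9.17; the list was called (camera, adjusted p = 4.2e-13; adjusted p = 0.15 with an estimated correlation). Of 15 monocyte and macrophage markers Csf1r passed (9 adjusted over the list alone; 3 with upper-quartile scaling), at 4.29 ± 4.79 and 22.3 ± 8.88 (camera, adjusted p = 1.3e-09; adjusted p = 0.15 with an estimated correlation). The list of dendritic cell markers was called higher with 0 of 7 past the threshold (1 adjusted over the list alone; camera, adjusted p = 0.015; adjusted p = 0.30 with an estimated correlation). The inhibitory receptor list was called higher (camera, adjusted p = 0.031; adjusted p = 0.48 with an estimated correlation) although its only called member, Nr4a1, was lower (2 rose and 1 fell adjusted over the list alone). The ribosomal protein list was called lower with 2 of 75 past the threshold, also adjusted over the list alone (camera, adjusted p = 0.0016; adjusted p = 0.63 with an estimated correlation), and the interferon-stimulated list with 0 of 46, also adjusted over the list alone (camera, adjusted p = 0.012; adjusted p = 0.72 with an estimated correlation).

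Features called in both comparisons with naive cells moved alike. In total RNA 494 features were higher in both, against 45.2 expected for independent lists of these sizes. Another 357 were lower in both, against 62.4; 0 moved in opposite directions. The fold changes correlated at r = 0.852 across features, which are not independent replicates, against 0.499 in 20 simulations of unchanged groups that shared the naive libraries. Their covariance was 0.614 against 0.0722 in the simulations. With 3 naive libraries the controls could not be split, so part of the excess may come from the shared controls.

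In small RNA, Mir155 and Mir146, both known to be induced in activated lymphocytes, rose in Hopx-low against naive cells. Mir155, on chromosome 16, 84714140 to 84714204, stood at 276 ± 56.7 in naive and 8353 ± 519.6 in Hopx-low cells (log2 fold change 4.93 ± 0.22, adjusted p = 9.5e-10), and Mir146, which is miR-146a, at 35.4 ± 7.72 and 667 ± 189 (4.18 ± 0.25). The other largest rises of ranked features were in Mir211 (4.81), Mir182 (4.28), Mir31 (3.73), Mir449c (3.26), Mir298 (2.97) and Mir138-2 (2.96). Mir32 fell from 232 ± 19.7 to 68.97 ± 16.1 (-1.76 ± 0.24, adjusted p = 0.00015), and the neighbouring Mir29a and Mir29b-1 on chromosome 6 fell by 1.04 and 1.38 on the log2 scale. Mir29b-2 (-1.35), Mir101a (-1.29), Mir669a-6 (-1.06), Mir669d (-1.14) and Mir669d-2 (-1.13) were the other largest falls of ranked features. The less abundant Mir143 fell more (-3.21, adjusted p = 0.0035). Copies with near-identical mature sequences, such as the Mir29b and Mir669 genes, share reads and their single values are uncertain. Limma called 70 of 510 features, 40 higher and 30 lower, but 32 and 52 with upper-quartile scaling and 74 and 1456 of 2220 features on the deposited scale; the former moved the median of all features from 0.0011 to -0.16. The commoner direction also turned without Hopx-low replicate 2, 29 higher and 32 lower. The count was 46 without Hopx-low replicate 1 and 38 without Hopx-low replicate 3.

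Of 102 measured members of the microRNA families fixed beforehand, 24 rose and 10 fell in Hopx-low cells (18 and 17 with upper-quartile scaling). The miR-17 to 92 group, which promotes lymphocyte growth, had 6 of 14 members higher (10 adjusted over the list alone; 3 with upper-quartile scaling and 4 with the replicate block), led by Mir18 (1.62 ± 0.21). The Mir182, Mir183 and Mir96 cluster rose in 3 of 3 members (2 with the replicate block) and the miR-23, 24 and 27 group in 5 of 6 (3 with upper-quartile scaling), with the same counts adjusted over the list alone, and Mir132 and Mir212 both rose (1.29 and 2.47). The let-7 and miR-98 family, which restrains growth, fell in 5 of 12 members, including Mirlet7g (-0.85 ± 0.20). That count was 8 adjusted over the list alone, 8 with upper-quartile scaling and 3 with quantile normalization. Of the miR-29 family 3 of 4 fell (4 adjusted over the list alone). Mir21a rose (2.63 ± 0.28), while Mir150, abundant in mature lymphocytes, stood at 118326 ± 44984 and 128912 ± 11703 and did not pass.

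In Hopx-high against naive cells, Mir21a, which is induced on T-cell activation, stood at 4895 ± 1359 in naive and 117993 ± 40783 in Hopx-high cells (log2 fold change 4.57 ± 0.28, adjusted p = 1.1e-08). Mir155 stood at 12299.7 ± 3160.0 (5.46 ± 0.22), and the other largest rises of ranked features were in Mir211 (6.11), Mir146 (5.69), Mir182 (5.55), Mir31 (5.17), Mir449c (5.08) and Mir298 (4.99). Mir150, at chromosome 7, 45121757 to 45121821, fell to 35284 ± 11373 (-1.72 ± 0.33, adjusted p = 0.0012). Mir503, Mir542 and Mir322, neighbours on the X chromosome, fell together (-1.85, -1.72 and -1.66), as did Mir32 (-1.58), Mir669a-6 (-1.58), Mirlet7b (-1.33) and Mir320 (-1.32). Limma called 158 of 510 features, 52 of them lower and the rest higher, but 64 of 165 higher with upper-quartile scaling and 67 higher and 70 lower with quantile normalization; the former moved the median of all features from 0.16 to -0.18. Of the 102 family members 44 rose and 17 fell (30 and 27 with upper-quartile scaling), with the miR-17 to 92 group higher in 12 of 14, also adjusted over the list alone (6 with upper-quartile scaling), and let-7 and miR-98 lower in 4 of 12 and higher in 1, also adjusted over the list alone (9 and 0 with upper-quartile scaling).

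**Figure D4:**
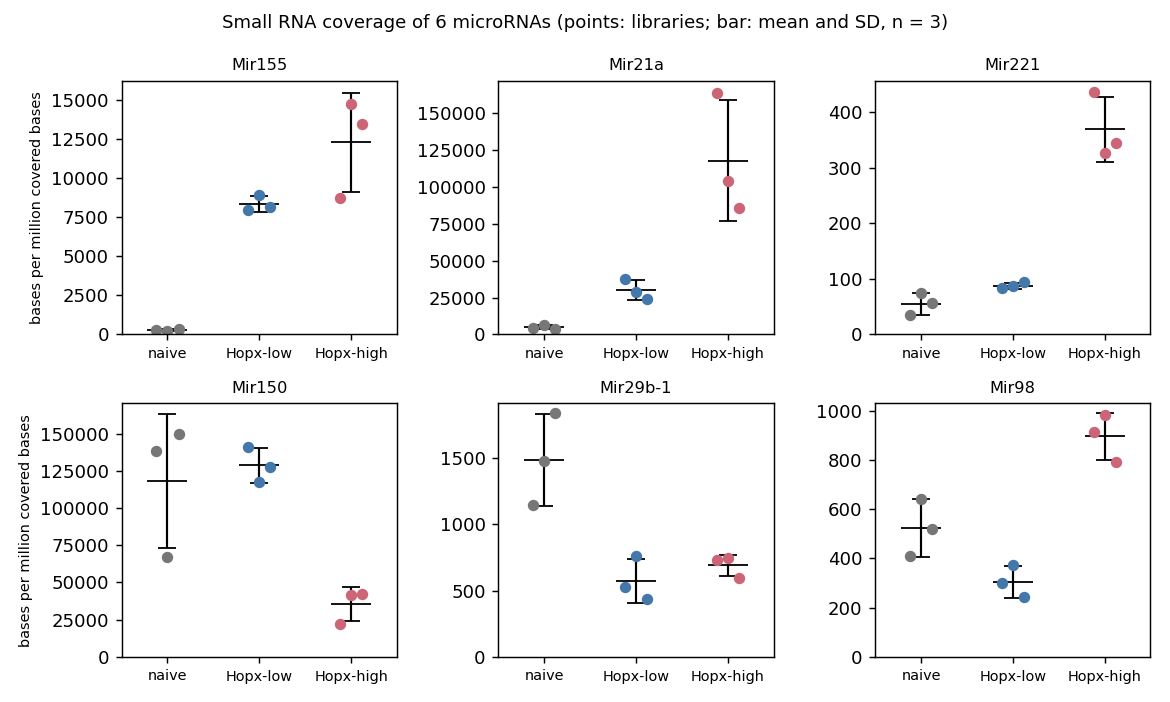
Coverage of 6 microRNAs in each small RNA library (y axes, bases per megabase covered, each from 0) by group (x axis), with points for libraries and bars for the mean and SD of 3. Mir155 and Mir21a were higher in both activated groups than in naive cells, Mir29b-1 was lower in both, and Mir150 averaged 118326, 128912 and 35284.

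In Hopx-high against Hopx-low cells, Mir21a rose (1.94 ± 0.28, adjusted p = 0.00057), and Mir221 and Mir222 rose too. These neighbours on the X chromosome, which target cell cycle inhibitors, stood at 88.1 ± 5.41 and 67.4 ± 8.23 in Hopx-low and 369 ± 58.8 and 272 ± 29.4 in Hopx-high cells (2.05 and 2.00). The other largest rises of ranked features were in Mir298 (2.02), Mir5123 (1.97), Mir210, a hypoxia-induced microRNA (1.90), Mir449c (1.81) and Mir223, a microRNA of myeloid cells (1.80; not called with upper-quartile scaling or with the replicate block). Mir150 fell (-1.92 ± 0.33, adjusted p = 0.0021), and the other falls were in Mir125a (-1.27), Mir542 (-1.25), Mir322 (-1.16), Mir503 (-0.94), Mir467d and Mir320 (-0.88 and -0.88) and the near-identical Mir26a-1 and Mir26a-2 (-1.08 and -1.10; neither called with the replicate block). Limma called 64 of 510 features, 55 higher and 9 lower, but 22 and 37 with upper-quartile scaling, 22 and 21 with quantile normalization and 28 and 9 on the deposited scale; the first moved the median of all features from 0.23 to -0.0016. Of the 102 family members 23 rose and 5 fell (13 and 13 with upper-quartile scaling), and the 5 of 14 members of the miR-17 to 92 group that rose (3 with the replicate block) were not called higher with that scaling, under which 1 fell. The count was 29 without Hopx-low replicate 1, 20 without Hopx-low replicate 3, 30 without Hopx-high replicate 1 and 23 without Hopx-high replicate 3.

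Between the 2 small RNA comparisons with naive cells, 38 features were higher in both, against 8.31 expected for independent lists, and 21 were lower in both, against 3.06. The covariance of fold changes was 1.000 against 0.131 in simulations of unchanged groups, with the same limit from shared controls. Mir98 was lower in Hopx-low and higher in Hopx-high cells than in naive cells, but its rise did not pass with upper-quartile scaling (0.33, adjusted p = 0.27).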

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

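The tests of what explains the excess of falls, the cell type markers and the histone genes were chosen only after the results were seen. Mir98, a member of the let-7 family, differed between the 2 activated groups by a test of the difference itself, and lay on either side of naive cells, though not under every scaling. It stood at 523 ± 116 in naive, 305 ± 65.1 in Hopx-low and 896 ± 95.6 in Hopx-high cells, with Hopx-high above Hopx-low by 1.57 ± 0.22 on the log2 scale (limma, adjusted p = 0.00057). Hopx-low lay below naive (-0.77, adjusted p = 0.029) and Hopx-high above it (0.79, adjusted p = 0.013). Mir98 was picked because it passed in every comparison, with opposite signs against naive cells. These limma p-values therefore restate the rule that picked it and are not separate support. With upper-quartile scaling the difference between the activated groups still passed (adjusted p = 0.0024), but the rise of Hopx-high over naive did not (0.33, adjusted p = 0.27).

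In total RNA, 35.7% of the features called between Hopx-high and naive cells were higher. With Lars2 and the histone genes left out of the library totals 54.3% were higher, and with Lars2 alone left out 1209 of 2649, but new totals shift every gene of a library alike, so this does not show the cause. With only replicates 1 and 2, and the totals unchanged, 617 were higher and 509 lower. Falls stayed commoner without both libraries richest in Lars2, 959 higher and 1290 lower, and without Hopx-high replicate 3, 814 higher and 896 lower. Lars2 took 3.01% ± 2.38 of the bases in naive and 10.4% ± 7.30 in Hopx-high cells, and the histones 1.05% ± 0.226 and 6.42% ± 0.730. Whether that larger share accounts for the excess of falls stays open. So does a loss of RNA from many genes in Hopx-high cells, which shares of a total cannot show.

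Lists of B cell and of monocyte and macrophage markers were called higher in Hopx-high than in Hopx-low cells, with 3 and 1 of 15 members past the threshold, but neither with an estimated correlation (adjusted p = 0.15 for both). If a lower share of CD4 T cells let in all other cell types alike, their markers would rise alike. A lower share from added B cells or macrophages alone would not raise CD8 markers, and was not tested. B cell markers moved above CD8 markers by 2.31 ± 0.43 on the log2 scale, but the B cell rise within that gap is the pattern itself. The 2 CD8 markers did not rise with them (median -0.87). Those 2 genes also had a median of -0.59 in Hopx-low against naive cells, so the gap cannot decide on a lower CD4 share. That 15 of 15 B cell markers and 15 of 15 monocyte and macrophage markers were positive restates the pattern and does not show where the RNA came from. The most abundant of these genes, Cd74, averaged 42.3 in naive, 93.8 in Hopx-low and 198 in Hopx-high cells, H2-Aa 30.3, 26.5 and 66.6, and Lyz2 7.60, 9.60 and 29.6. RNA from other cells and expression by the activated T cells themselves both stay open.

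Histone genes were higher in Hopx-high than in Hopx-low cells. Reads shared between near-identical histone genes would leave the family sum unchanged if each read was counted once, which is not known. The summed share was higher by 1.45 ± 0.14 on the log2 scale. A test that summed members with similar levels was tried first, at 3 tolerances from 1.1 to 1.5 times, and left 57 of 60, 55 of 58 and 37 of 40 groups higher and 0 lower; the summed share replaced it after those results were seen. A higher yield of all RNA without poly(A) tails would raise small nucleolar RNAs too, but their median was -0.14, with an upper quartile of 0.08, against 1.75 for the histones. These values cannot exclude a yield that rose for histone RNA and not for small nucleolar RNAs. More dividing cells in the Hopx-high group is a hypothesis that these data leave open: 49 of 49 proliferation genes were positive.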

How the results depend on the processing

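Tests on the deposited scale, with totals without Lars2 or histones, without both libraries richest in Lars2, on replicates 1 and 2, on annotated microRNAs, and on scaling for lists or families and left-out libraries for families were chosen only after the results were seen. Under the alternatives named beforehand, 9802 tests of named total RNA genes stayed on the same side of the threshold. Another 416 lost the call, the rest gained it and 0 reversed with a call. Of small RNA features 3405 stayed, 250 lost the call and 59 gained it, and of lists 960 stayed, 68 lost it and 13 gained it. A test called in neither fit counted as having stayed even where its direction turned. For total RNA, in the order Hopx-low against naive, Hopx-high against naive and Hopx-high against Hopx-low, the counts were 522, 1540 and 118 with a test against a fold of 1.2, and 5.0e+02 to 2 digits, 1126 and 71 with only replicates 1 and 2, which has fewer libraries. Without trend and robust settings they were 614 for the first and 159 for the last, and a pseudocount of 0.1 gave 154 for the last, 80 of them lower. Leaving out 1 library gave 576 to 753, 1710 to 3132 and 127 to 278. For small RNA the deposited scale, on which a feature without coverage takes a value set by depth, gave 1530 (74 higher and 1456 lower), 103 and 37. A fold of 1.2 gave 35 and 17 for the first and last, adjusted p below 0.1 gave 120 for the first, and for the last no trend gave 14 and a fold of 2 gave 34; the causes were not tested. Leaving out 1 library gave 38 to 68, 118 to 160 and 20 to 61. Called lists numbered 16 for Hopx-high against naive with upper-quartile scaling, 5, 5 and 2 with an estimated correlation, 2 with fry for the last, and 17 to 18, 16 to 20 and 9 to 12 without 1 library. Called family members ranged from 21 to 33, the lowest without Hopx-low replicate 3, 51 to 60, and 12 to 27; the last count was 16 without Hopx-low replicate 1, 12 without Hopx-low replicate 3, 18 without Hopx-high replicate 1 and 16 without Hopx-high replicate 3. With the replicate block the counts were 970, 2677 and 255 in total RNA, 66, 137 and 54 in small RNA, 34, 57 and 23 for families and 17, 18 and 12 for lists. Same-numbered libraries did not deviate together in every pair. Correlations ran from -0.13 to 0.19 in total RNA, with 3 of 9 above 0.1, and from -0.33 to 0.09 in small RNA, with 0 of 9. Among pairs with other numbers 2 of 18 and 6 of 18 were above 0.1. Same-numbered Hopx-low and Hopx-high libraries correlated at 0.19, 0.14 and 0.06 in total RNA, against -0.15 to 0.057 for other numbers of these groups. In small RNA the values were -0.04, 0.09 and -0.06, against -0.16 to 0.19. The main fit thus may miss a pairing of the activated groups in total RNA. The numbers did track sex in total RNA, with Xist coverage in replicate 3 of each group alone, and the main fit did not model this. Whether they pair the libraries beyond sex stays open. Low levels rest on few reads, and simulated 1.5-fold changes were recovered in 1.49% of cases or fewer in total RNA.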

Other observations

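All tests of small nucleolar RNAs and the tests of other splits in this part were chosen only after the results were seen. Small nucleolar RNAs, which guide the modification of ribosomal RNA, went both ways in Hopx-high against naive cells: of 94 measured, 11 rose and 24 fell (11 and 14 with upper-quartile scaling), and the class was not called by camera. Snora81 averaged 3666 ± 1087 in naive and 762 ± 364 in Hopx-high cells, and Snord82 65.4 ± 28.7 and 331 ± 72.4; these were picked after their values were seen. In Hopx-low against naive cells 2 rose and 6 fell, and between the activated groups 0 changed by limma. Gas5, a host gene of such RNAs, rose in Hopx-high cells (log2 fold change 1.19 ± 0.24, adjusted p = 0.0016).

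The 6 libraries of each comparison can be split in 10 ways, the real one included, which are too few for a share under 0.05. In each comparison only 1 split, the real one, gave a count as large. In total RNA the real counts were 950, 2666 and 242 for Hopx-low against naive, Hopx-high against naive and Hopx-high against Hopx-low, and the highest of the other splits gave 0, 0 and 84. In small RNA the real counts were 70, 158 and 64, and the highest others 0, 0 and 0. For gene lists the real counts were 17, 18 and 12 and the highest others 13, 15 and 10. Camera at the preset correlation thus called nearly as many lists in some other splits, so these list counts hardly set the real groups apart. Every other split mixed libraries of both real groups on each side. Part of the real difference therefore stayed in it, while the spread within its sides grew. Such splits do not show what unchanged groups would give, so neither the list counts nor the feature counts decide on the real grouping.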
